A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

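RNA was measured on 11 Affymetrix yeast arrays (YG-S98). The samples were 3 anaerobic, glucose-limited chemostat cultures and 2 retentostat cultures, each of the latter sampled after 2, 9, 16 and 22 days. Per the labels' protocols, broth was frozen at once in liquid nitrogen, total RNA was extracted with hot phenol, and biotin-labelled targets were made with the manufacturer's 1-cycle assay. The deposited values are linear array intensities; per the submitters' processing notes they were made with GCOS 1.2. The settings of that software and its scaling target are not given in the sources used here. The deposited means, after 2% of the values at each end of an array were trimmed, differed between arrays by 0.0218% at most, so the deposited scaling was kept. Detection calls were not used.

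The file holds 9335 probe sets, 60 of them controls. Of the rest, 6504 carry 1 gene, 328 several and 2443 none. Only probe sets with 1 gene were tested. Their genes were looked up in the annotation of the S288C reference assembly R64, used for names and biotypes only, and no symbol changed. Values under 12 were set to 12 and the log2 was taken. Of 5656 genes, 315 had more than 1 probe set, and the one with the highest mean was kept. After 59 genes at the floor on all arrays were dropped, 5597 genes were tested, 5434 of them protein-coding. Some probe sets cannot separate close copies, such as HXT6 and HXT7, HYP2 and ANB1, or the seripauperins, so their signal cannot be assigned to a gene with certainty.

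A single linear model with a mean for each of the 5 groups was fitted with limma 3.58.1 in R 4.3.3 (6 residual and 4.85 prior degrees of freedom). Each retentostat day was compared with the chemostat, consecutive days with each other, and day 22 with day 2. Moderated F tests covered all 5 groups and the 4 retentostat days. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Words such as rose and fell are used for genes that passed; other genes are given as values. SE is the standard error of a log2 change, and levels are means ± SD of the intensities. The retentostat arrays of different days share their cultures. The model treats them as independent.

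Whole lists were tested with camera, also from limma, at a preset correlation between genes of 0.01, for day 2 and day 22 against the chemostat and day 22 against day 2. Its 93 p-values (31 lists, 3 comparisons) were adjusted together. This test asks whether the genes of a list moved differently from all other genes, so a list can be lower in the test while its own median is above 0. With a correlation estimated for each list the same test makes 0 calls, and its adjusted p is given beside the first. The rotation test fry asks instead whether the genes of a list move on balance in 1 direction. For each list, the members that passed over all genes were counted, and again those that passed when p-values were adjusted over the list alone.

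The lists cover carbon metabolism (glycolysis and alcoholic fermentation, hexose transport, trehalose and glycogen, the tricarboxylic acid cycle, the glyoxylate cycle with gluconeogenesis and alternative carbon, beta-oxidation and peroxisome, the respiratory chain and ATP synthase), stress and turnover (heat shock proteins and chaperones, the Msn2/Msn4 response, stationary phase and quiescence, oxidative stress defence, autophagy, proteasome and ubiquitin, vacuolar proteases), anaerobic life (ergosterol biosynthesis, anaerobic cell wall and sterol uptake, seripauperins), and growth (cell cycle regulators, DNA replication and histones, cell wall, ribosome biogenesis, RNA polymerase I and III, translation factors, aminoacyl-tRNA synthetases, cytosolic and mitochondrial ribosomal proteins). The remaining lists are amino acid biosynthesis, nitrogen catabolite repression, phosphate starvation, meiosis and sporulation, and mating and pheromone response.

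The tests, lists, threshold, floor and rule for naming genes were chosen before the data were examined. By that rule, the 8 largest rises and falls were named among genes that passed, had a standard name, and whose arrays did not overlap between the groups (5 of each for day 9, day 16 and consecutive days). Up to 2 risen and 2 fallen members of each list, up to 4 genes at the floor in every array of a group, and a panel of 12 genes were named as well. Where a list had no member that passed, up to 2 members could be given as values. Chosen after the data were seen were the largest changes of protein-coding genes alone, the classes of non-coding RNA, lists of iron-regulated, haem-activated and glucose-repressed genes, and the 3 alternatives that restrict the genes to nuclear protein-coding ones, leave out the 2 arrays of lowest actin ratio, or use the actin ratio as a covariate.

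Alternatives chosen in advance were quantile normalization, scaling to 1 median, no floor and a floor of 50, only genes with a mean of at least 50, no filter, every probe set on its own, the replicate number as a fixed block, the culture as a random block, trend and robust moderation, fits of only the arrays compared, a 2-fold threshold, each array left out in turn, camera with an estimated correlation, and fry. The method was tested on simulated data with 200 changed genes of 5597. It recovered 62% of the 2-fold and 92% of the 4-fold changes for day 2 against the chemostat, with 7 false calls. For day 22 against the chemostat it recovered 67% and 100%, with 11 false calls, for day 22 against day 2 60% and 96%, with 9, and for day 22 against day 16 58% and 96%, with 6. A shifted list was called, and 0 of the other lists were. The noise was simulated as independent between genes and between arrays, and the 200 changed genes were kept clear of the floor. The simulation therefore does not test calls of genes near the floor or of lists whose genes correlate, such as the seripauperins (estimated correlation 0.88). Nor does it test what follows from retentostat days that share their cultures.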

Results

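Transcript levels were measured on 11 whole-genome oligonucleotide arrays in the prototrophic laboratory yeast strain CEN.PK113-7D, grown without oxygen and with glucose as the limiting nutrient. The comparisons ask how gene expression changes as growth slows to almost nothing while the cells stay alive and fed. The starting point was a set of 3 independent chemostat cultures with a specific growth rate of 0.025 per hour. The remaining 8 arrays came from 2 independent retentostats, vessels in which a filter in the outflow holds the cells back while fresh medium keeps entering. These cultures were sampled after 2, 9, 16 and 22 days, when the specific growth rates were 0.0084, 0.0024, 0.0011 and 0.00063 per hour. Arrays of different days therefore come from the same pair of cultures, and each retentostat day is represented by 2 arrays.

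The values are array intensities, and 5597 genes were tested. Within a group, the log2 values of any pair of arrays correlated over genes with r between 0.968 and 0.992. Control probe sets differed between the groups. The ratio of the actin 5' to the actin 3' signal, a measure of RNA integrity, lay between 0.766 and 0.796 in the chemostats. It was 0.748 and 0.709 at day 2, 0.669 and 0.734 at day 9, 0.736 and 0.472 at day 16, and 0.571 and 0.341 at day 22. The same ratio for a second control gene, TBP, did not fall in this way. It lay between 0.466 and 0.562 in the chemostats and was 0.443 and 0.604 at day 2. At day 9 it was 0.489 and 0.461, at day 16 0.563 and 0.568, and at day 22 0.537 and 0.476. A loss of RNA integrity with time is therefore read from actin alone. The number of arrays limits the precision of all values given here.

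**Figure D1:**
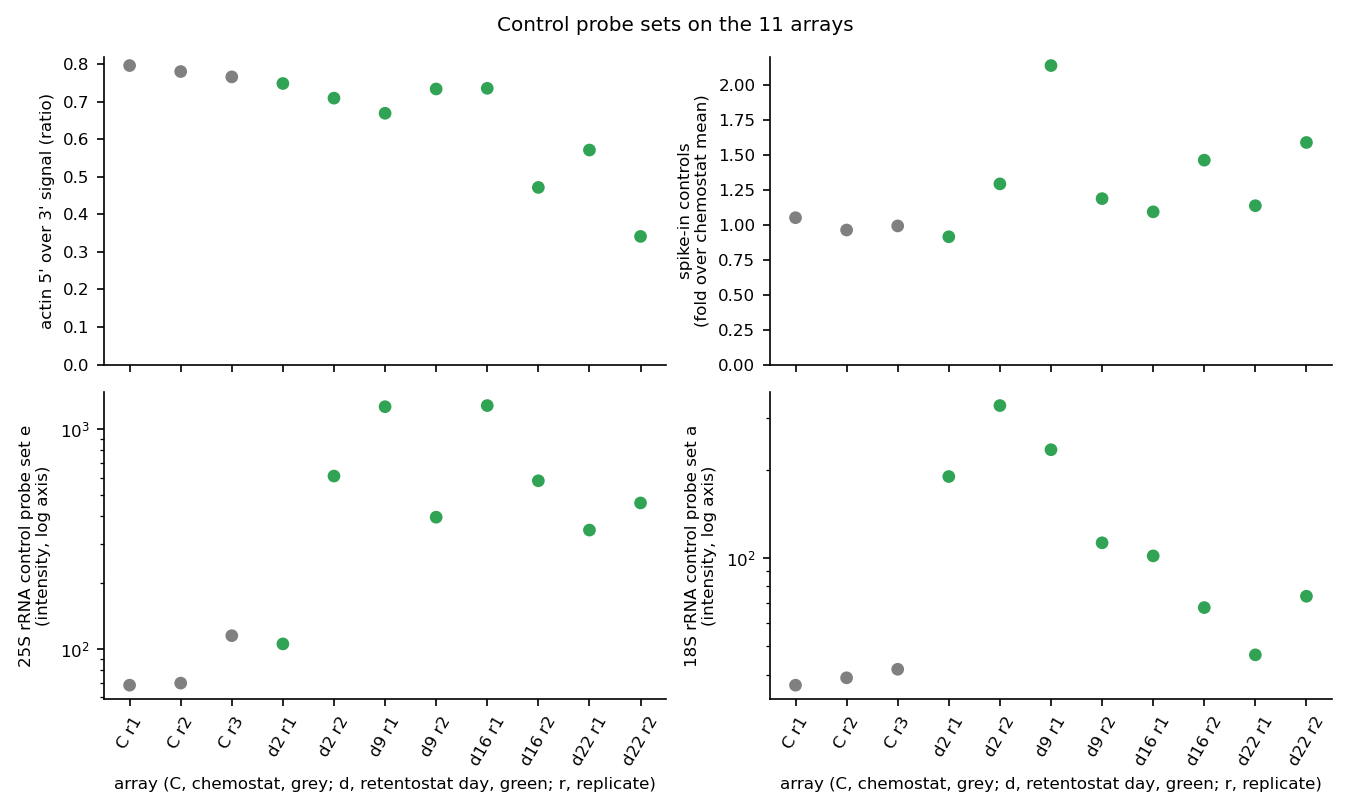
Control probe sets on each of the 11 arrays (horizontal axis): the actin 5' to 3' ratio, the signal of the 9 spike-in probe sets as fold over the chemostat mean, and the intensity (log axis) of a 25S and an 18S ribosomal RNA probe set. Points are single arrays; the lowest actin ratio is 0.341 (day 22 replicate 2) and the highest spike-in signal is 2.14-fold (day 9 replicate 1).

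Expression changed over the 5 groups for 2210 genes (39.5% of those tested), and over the 4 retentostat days for 660 genes (11.8%; limma moderated F test). Against the chemostat, 87 genes had changed at day 2, 2127 at day 9, 2206 at day 16 and 2386 at day 22. Without chemostat replicate 2 the count over the 5 groups was 1427. The count over the retentostat days depended on single arrays. It was 202 without day 2 replicate 1, 237 without day 2 replicate 2, 270 without day 22 replicate 2, 380 without day 22 replicate 1, 382 without day 16 replicate 2, 397 without chemostat replicate 1, 423 without chemostat replicate 2 and 1366 without day 9 replicate 2.

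The balance between higher and lower genes depended on how the arrays were scaled to each other. With the deposited scaling the median log2 change of all genes was 0.04 at day 2, 0.06 at day 9, 0.14 at day 16 and 0.23 at day 22 against the chemostat, and 0.19 for day 22 against day 2. At day 22, 1782 genes were higher and 604 lower (74.7% higher). After quantile normalization the split was 1215 to 1009 (54.6% higher), and after scaling to 1 median it was 1015 to 1125 (47.4% higher). For that reason, changes at day 16 and day 22 are given below relative to the median of all genes; the tests were made on values without this shift. Changes at days 2 and 9 are given as fitted, and so are all fold changes of genes at the floor.

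**Figure D2:**
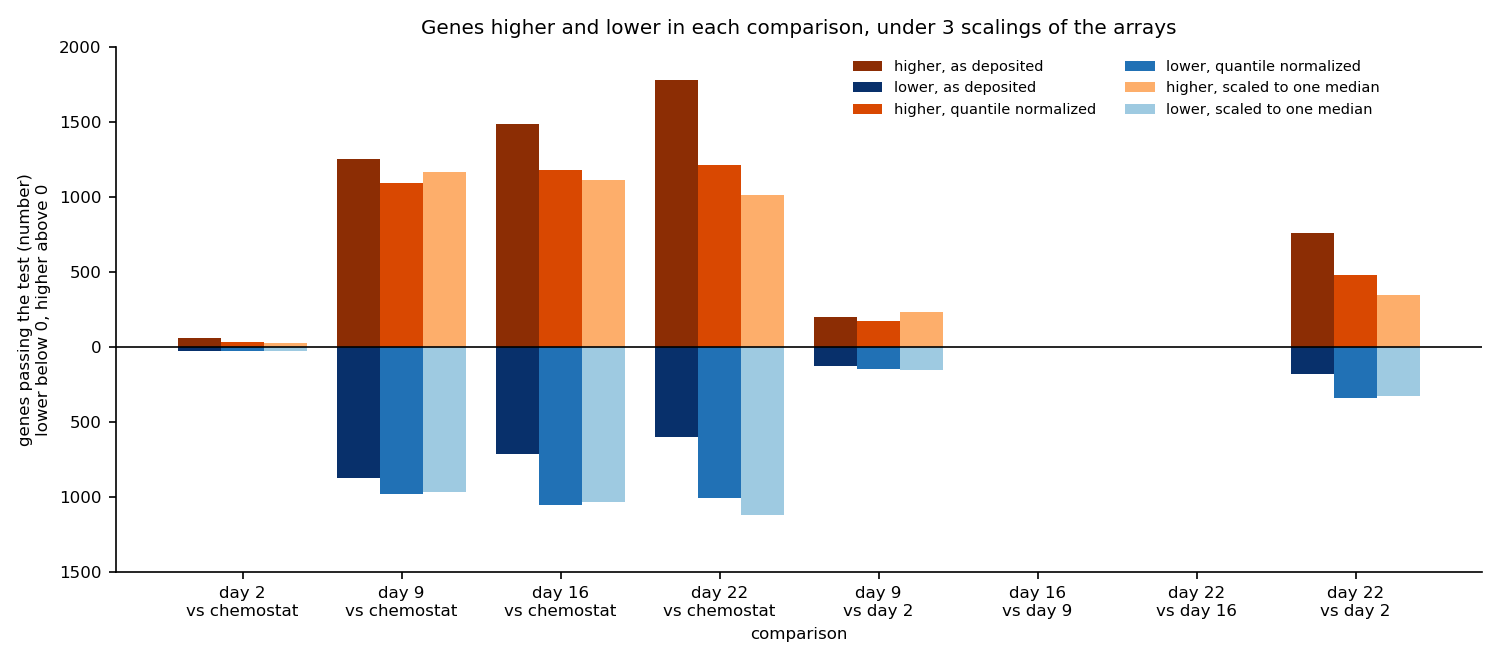
Number of genes higher (above 0) and lower (below 0) in each of the 8 comparisons, with the deposited scaling, after quantile normalization and after scaling to 1 median. At day 22 against the chemostat, 1782 genes were higher with the deposited scaling and 1015 after scaling to 1 median, where 1125 were lower.

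The first comparison asks what had changed after 2 days in the retentostat. The largest rise was that of RNR3, the minor isoform of the large subunit of ribonucleotide reductase, from an intensity of 284 ± 65.2 (SD, n = 3) to 1406 ± 91.0 (n = 2; log2 change 2.33 ± 0.21 SE, adjusted p = 0.00068). The largest fall was that of FLO11, which encodes a cell-surface glycoprotein used in adhesion, from 1641 ± 201 to 174 ± 20.7 (−3.23 ± 0.23, adjusted p = 0.00018). PIR3, a cell wall protein, rose by 1.83 ± 0.19 (adjusted p = 0.0022), and ALD6, the cytosolic aldehyde dehydrogenase that makes acetate, fell by 2.32 ± 0.21 (adjusted p = 0.00068). Stress-related genes also rose, among them HSP30, a plasma membrane stress protein (1.72 ± 0.31, adjusted p = 0.026), and SSA3, a stress-induced chaperone (1.40 ± 0.21, adjusted p = 0.015). CYC7, the hypoxic isoform of cytochrome c, rose by 1.84 ± 0.31 (adjusted p = 0.019).

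Other large changes at day 2 were rises of SHH3 (1.74), FMP16 (1.45) and YRO2 (1.43). Among the falls were HXT2, a high-affinity glucose transporter (−2.48), PGM1, the minor phosphoglucomutase (−1.72), DAN4, a cell wall mannoprotein of anaerobic cells (−1.52), the ammonium permease MEP3 (−1.44), the cell wall transglycosylase UTR2 (−1.38) and AIM20 (−1.36). The naming rule required that, for each of the genes named so far, every array of the higher group lay above every array of the lower group. In all, 59 genes were higher and 28 lower, and 913 genes had an unadjusted p under 0.05. The split was 33 to 25 after quantile normalization and 28 to 29 after scaling to 1 median.

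These day 2 calls were fragile. The count fell to 4 without chemostat replicate 1 and to 4 without chemostat replicate 2. It was 6 without day 2 replicate 1, 22 without day 2 replicate 2, 15 without either day 22 array and 32 without either day 16 array, and it was 158 without either day 9 array. Of the 35 genes named for day 2 that passed, 4 (RNR3, PIR3, FLO11 and ALD6) passed with each array left out in turn. When only the chemostat and day 2 arrays were fitted, none of the 35 passed and limma called 0 genes. The number of the 35 that passed was 4 without chemostat replicate 1, 4 without chemostat replicate 2, 28 without chemostat replicate 3, 5 without day 2 replicate 1 and 9 without day 2 replicate 2. It was 16 without either day 16 array and 9 without either day 22 array.

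Gene lists fixed in advance were compared with all other genes (camera, preset correlation). At day 2, 9 lists were higher and 10 lower, and none of them was called with an estimated correlation. The Msn2/Msn4 general stress response was the most clearly higher, with 5 of 45 genes risen, or 23 adjusted over the list alone and 2 after scaling to 1 median (median log2 change 0.60, adjusted p = 1.8e-13; adjusted p = 0.45 with an estimated correlation). Of the heat shock proteins and chaperones, 5 of 31 rose, or 12 adjusted over the list alone and 3 after scaling to 1 median (adjusted p = 4.4e-09; adjusted p = 0.31 with an estimated correlation). The respiratory chain and ATP synthase list had 2 of 40 genes risen, or 17 adjusted over the list alone and 1 under either other scaling (adjusted p = 4.2e-11; adjusted p = 0.48 with an estimated correlation). In the list for stationary phase and quiescence 3 of 24 rose, or 11 adjusted over the list alone (adjusted p = 9.0e-07; adjusted p = 0.45 with an estimated correlation). Autophagy had 2 of 35 genes risen, ATG39 (1.34) and ATG1 (0.98), or 4 adjusted over the list alone (adjusted p = 1.0e-05; adjusted p = 0.43 with an estimated correlation).

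Amino acid biosynthesis was the most clearly lower list at day 2. A single gene of 79 fell, GDH1 (−1.15), a call that ended under both other scalings, where 1 other member fell, and 2 fell when adjusted over the list alone (median −0.36, adjusted p = 1.3e-11; adjusted p = 0.47 with an estimated correlation). Among cell cycle regulators 2 of 35 fell, the late-mitotic transcription factor SWI5 (−1.14, not called after quantile normalization) and the G1 cyclin CLN1 (−0.96), or 5 adjusted over the list alone (adjusted p = 5.3e-07; adjusted p = 0.057 with an estimated correlation). Cytosolic ribosomal proteins had 1 of 81 fallen, RPS22B (−0.82), and 1 adjusted over the list alone (adjusted p = 5.3e-06; adjusted p = 0.65 with an estimated correlation). No aminoacyl-tRNA synthetase of 21 passed over all genes and 2 fell adjusted over the list alone (adjusted p = 1.5e-05; adjusted p = 0.58 with an estimated correlation). For the seripauperins, a family of cell wall mannoproteins made without oxygen, 0 of 10 passed and 1 fell adjusted over the list alone (median −0.76, adjusted p = 5.8e-05, and adjusted p = 0.58 with an estimated correlation). Of the genes for anaerobic cell wall and sterol uptake 2 of 24 fell, DAN4 and the mitochondrial carrier AAC3 (−1.17), and 2 adjusted over the list alone (adjusted p = 0.0029; adjusted p = 0.15 with an estimated correlation).

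The remaining lists called at day 2 rested on small shifts. Ergosterol biosynthesis (median −0.25, adjusted p = 0.0017; adjusted p = 0.54 with an estimated correlation), ribosome biogenesis (−0.11, adjusted p = 0.0018; adjusted p = 0.76 with an estimated correlation) and translation factors (−0.19, adjusted p = 0.0026; adjusted p = 0.60 with an estimated correlation) were lower with no member past the threshold, over all genes or adjusted over the list alone. Mitochondrial ribosomal proteins were higher, also with no member past the threshold (0.15, adjusted p = 0.012; adjusted p = 0.70 with an estimated correlation). Proteasome and ubiquitin genes were higher with 1 member risen, RPN4 (0.74), a call that ended under both other scalings (adjusted p = 0.0017; adjusted p = 0.55 with an estimated correlation). Oxidative stress defence was higher with 4 of 37 risen, among them OYE3 (1.37), or 7 risen and 1 fallen adjusted over the list alone and 1 risen under either other scaling (adjusted p = 0.031; adjusted p = 0.60 with an estimated correlation). Trehalose and glycogen metabolism was higher as a list (median 0.27, adjusted p = 0.035; adjusted p = 0.60 with an estimated correlation), although the only member past the threshold, PGM1, fell (4 rose and 2 fell adjusted over the list alone). DNA replication and histones was lower as a list (−0.09, adjusted p = 0.029; adjusted p = 0.60 with an estimated correlation), although its only member past the threshold, also adjusted over the list alone, RNR3, rose. The rotation test fry called 8 of the 19 lists, those for heat shock, Msn2/Msn4, stationary phase, autophagy, proteasome, respiratory chain, anaerobic cell wall and cell cycle.

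Several of these list calls depended on 1 array. That of trehalose and glycogen metabolism ended without chemostat replicate 2 or day 2 replicate 1. DNA replication and histones was not called without chemostat replicate 3 or day 2 replicate 1, nor was oxidative stress defence without chemostat replicate 2 or day 2 replicate 2, with only the arrays compared, without the 2 arrays of lowest actin ratio, or with that ratio as a covariate. Mitochondrial ribosomal proteins lost their call without chemostat replicate 1 or chemostat replicate 2, the proteasome list without day 2 replicate 1, and translation factors without day 2 replicate 2. The 12 lists without a call at day 2 included glycolysis and alcoholic fermentation, where 1 of 23 genes rose (median 0.07, mean −0.03, adjusted p = 0.92), the cell wall list, where 1 of 47 rose and 4 fell (median 0.01, mean −0.10, adjusted p = 0.19), and phosphate starvation, where 0 of 16 passed (adjusted p = 0.43).

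**Figure D3:**
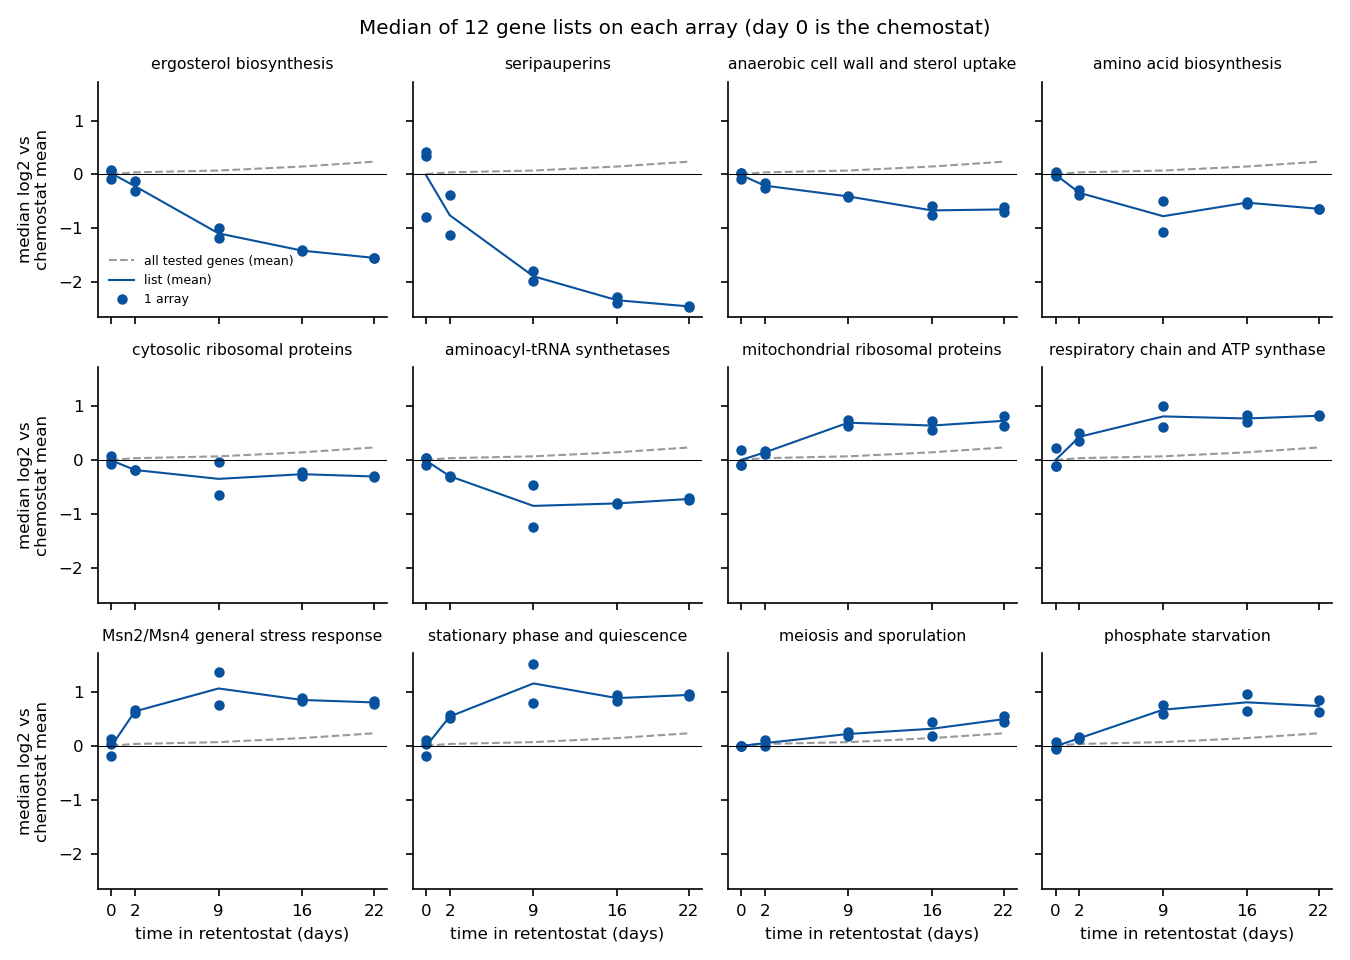
Median log2 intensity, relative to the chemostat mean, of 12 gene lists on each array (points) and averaged over the arrays of a day (solid line), against time in the retentostat; the dashed line is the median of all tested genes. At day 22 the fitted median change was −1.49 for the ergosterol genes and −2.43 for the seripauperins; after quantile normalization the day 22 calls of the cytosolic ribosomal proteins and of meiosis and sporulation were lost.

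By day 9 the changes involved a large share of the genome. The largest falls were those of FIT2 and FTR1, both of iron uptake. FIT2, a cell wall mannoprotein that holds iron-bound siderophores, dropped from 3583 ± 517 (SD, n = 3) in the chemostat and 3403 ± 23.5 (n = 2) at day 2 to 249 ± 32.7 at day 9 (−3.84 ± 0.24 SE against the chemostat, adjusted p = 1.4e-05). FTR1, the high-affinity iron permease, went from 968 ± 167 and 711 ± 194 to 67.3 ± 8.20 (−3.84 ± 0.21, adjusted p = 9.5e-06). SIT1, a siderophore transporter (−2.96), the alcohol acetyltransferase ATF2 (−2.87) and FLO11 (−3.19) fell as well. The largest rises were those of SPG1, a stationary phase gene (4.15 ± 0.44, adjusted p = 0.00014), the spliceosomal RNA SNR14 (4.13), HSP30 (3.66), SHH3 (3.31) and RNR3 (3.30). In total 1255 genes were higher and 872 lower than in the chemostat. The split was 1092 to 985 after quantile normalization and 1165 to 969 after scaling to 1 median, and without day 9 replicate 1 the count was 1250.

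Day 16 was likewise compared with the chemostat. FTR1 (−3.77 ± 0.21, adjusted p = 7.5e-06), FIT2 (−3.70), SIT1 (−3.47), HES1, a homologue of oxysterol-binding proteins (−3.45), and the seripauperin PAU23 (−3.37) fell most, relative to the median of all genes. SNR14 (5.35), SNR71 (4.08), SNR45 (4.07), SPG1 (4.03) and SNR7-L (3.54) rose most. SNR14 and SNR7-L are spliceosomal RNAs, and SNR71 and SNR45 are small nucleolar RNAs. There were 1488 higher and 718 lower genes, 1179 and 1053 after quantile normalization, and 1110 and 1035 after scaling to 1 median. Without day 16 replicate 2, an array with an actin ratio of 0.472, the count was 1181. Each of the 10 genes named at day 9 and the 10 at day 16 passed with each array left out in turn.

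**Figure D4:**
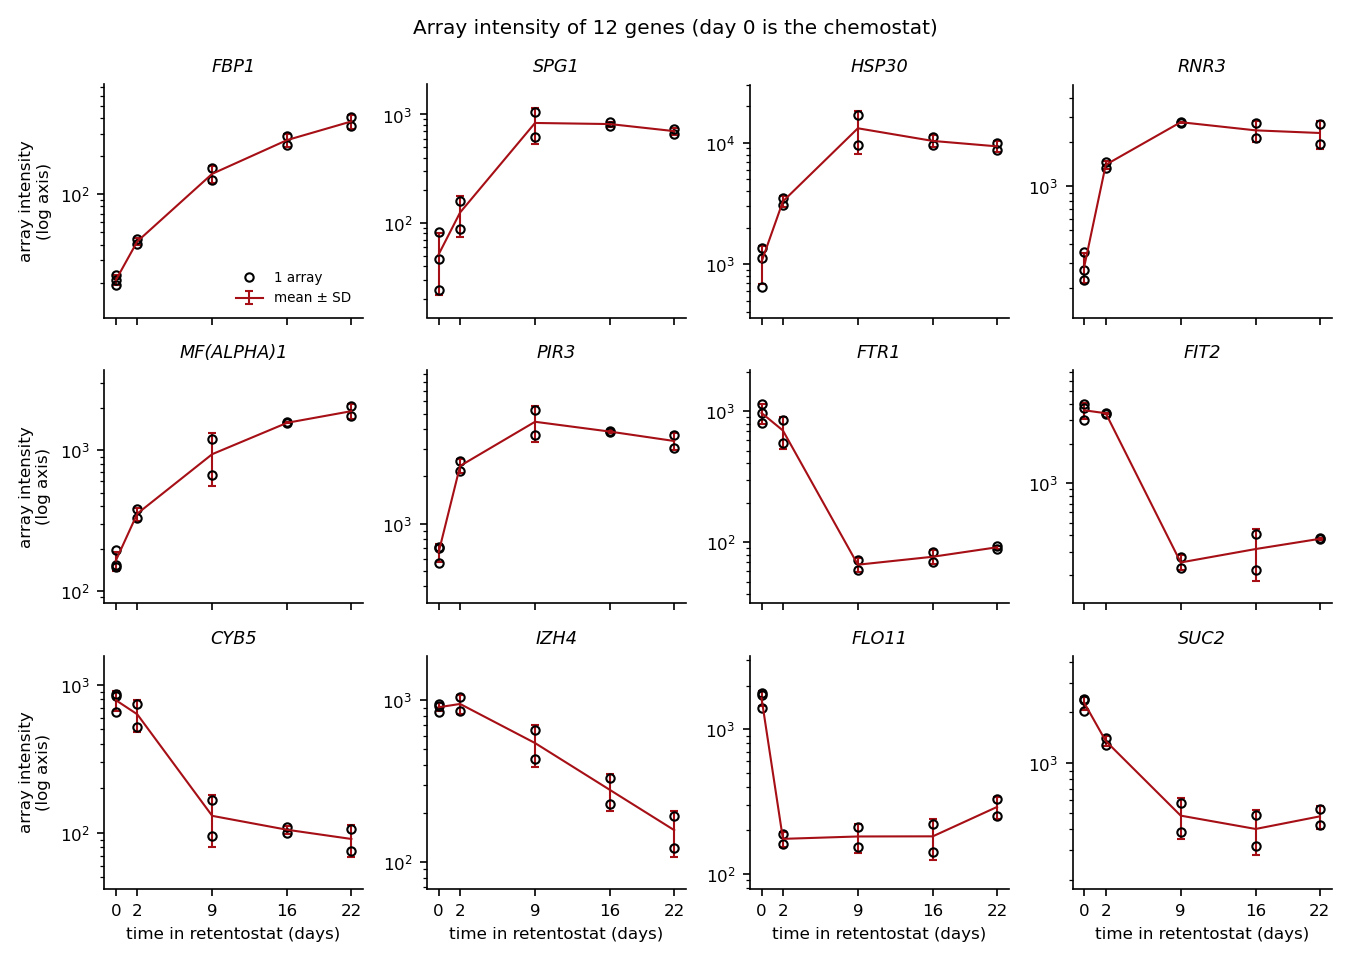
Array intensity (log axis) of 12 genes against time in the retentostat; circles are single arrays and the line joins the mean ± SD of each day. FIT2 went from 3403 at day 2 to 249 at day 9, and FBP1 from 20.9 in the chemostat to 375 at day 22.

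Day 22 against the chemostat is the widest span of growth rates. Genes of sterol synthesis and anaerobic cell wall proteins were lower, as were several of iron uptake, while the transcripts of FBP1 and SPG1 and many non-coding RNAs were higher. FBP1, the gluconeogenic fructose bisphosphatase, rose from 20.9 ± 1.85 (SD, n = 3) to 375 ± 46.2 (n = 2; 3.93 ± 0.17 SE relative to the median of all genes, adjusted p = 4.3e-07). SPG1 rose by 3.71 ± 0.44 (adjusted p = 9.6e-05). Among the largest falls were those of PAU23 (−3.71 ± 0.39, adjusted p = 0.00011), FTR1 (−3.62 ± 0.21, adjusted p = 6.0e-06), FIT2 (−3.47 ± 0.24, adjusted p = 8.9e-06) and CYB5, the cytochrome that donates electrons in sterol synthesis (−3.36 ± 0.27, adjusted p = 2.3e-05). PBI1 (−3.17), ATF2 (−3.11) and SIT1 (−3.02) also fell, as did the vacuolar lipase ATG15 (−3.50), whose call was lost without day 22 replicate 2.

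Among protein-coding genes, chosen after the non-coding RNAs had filled most places among the largest rises, the next in size were the alpha-factor gene MF(ALPHA)1 (3.30 ± 0.24, adjusted p = 6.5e-06), HSP30 (2.99), the aryl-alcohol dehydrogenase homologue AAD10 (2.83), GIT1, a permease for glycerophosphoinositol (2.83), RNR3 (2.80) and the polyamine exporter TPO2 (2.73). Small RNAs led the ranking of all genes. The small nucleolar RNAs SNR45, SNR71 and SNR128 rose by 4.68 ± 0.35, 4.39 ± 0.33 and 3.94 ± 0.20 (adjusted p = 7.4e-06, 7.4e-06 and 1.3e-06). The spliceosomal RNAs SNR14, SNR7-L and SNR6 rose by 5.36 ± 0.78, 4.03 ± 0.49 and 3.75 ± 0.68 (adjusted p = 0.00036, 0.00012 and 0.0012). Of genes at the floor of 12 in every chemostat, SNR3 was, as fitted, at least 10.4-fold higher, PUL3, a siderophore transporter, at least 7.10-fold and SNR35 at least 6.35-fold. WHI5, an inhibitor of cell cycle entry, was at the floor at day 22 and at least 7.16-fold lower, a call lost without either day 22 array.

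Sterol and anaerobic cell wall genes were lower at day 22. Of 25 ergosterol biosynthesis genes, 22 fell and none rose, with the same counts adjusted over the list alone (median −1.73 relative to all genes, adjusted p = 9.8e-20; adjusted p = 0.069 with an estimated correlation). ERG12, mevalonate kinase, fell by 2.76, although its 4 probe sets did not all have the same sign. All 10 seripauperins fell, and all 10 adjusted over the list alone (median −2.67, adjusted p = 1.4e-10; adjusted p = 0.45 with an estimated correlation), PAU23 and PAU15 (−2.99) most. Because family members are nearly identical, signal cannot be assigned to single genes with certainty. In the list for anaerobic cell wall and sterol uptake 13 of 24 fell and 2 rose, with the same counts adjusted over the list alone (median −1.07, adjusted p = 1.1e-07; adjusted p = 0.052 with an estimated correlation). SCM4 (−2.88) and IZH4, a membrane protein of zinc homeostasis (−2.79), fell most, while the hypoxic cytochrome c oxidase subunit COX5B rose by 0.81. The actin ratio fell over the same days as these genes.

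Genes of protein synthesis were lower. In amino acid biosynthesis 41 of 79 fell and 5 rose, or 46 and 5 adjusted over the list alone (median −0.86, adjusted p = 4.2e-15; adjusted p = 0.45 with an estimated correlation). The asparagine synthetase gene ASN1 (−2.41) and the cystathionine gamma-lyase gene CYS3 (−2.14) fell most. Of 21 aminoacyl-tRNA synthetases 14 fell, or 17 adjusted over the list alone, TYS1 (−1.47) and CDC60 (−1.19) most (list adjusted p = 2.3e-08; adjusted p = 0.48 with an estimated correlation). Among 35 translation factors 11 fell and 1 rose, or 9 and 1 adjusted over the list alone and 18 and 0 after scaling to 1 median (adjusted p = 6.1e-07; adjusted p = 0.45 with an estimated correlation), with HYP2 (−2.40) and TEF4 (−2.00) lowest. HYP2 has a near-identical copy, ANB1, so its signal cannot be assigned with certainty. Cytosolic ribosomal proteins were lower as a list, with 13 of 81 fallen and 2 adjusted over the list alone (median −0.50, adjusted p = 2.6e-08; adjusted p = 0.60 with an estimated correlation). That list was not called after quantile normalization, and 47 of its genes fell after scaling to 1 median. RPP2A fell by 1.70. In ribosome biogenesis 14 of 131 fell and 3 rose, or 6 and 1 adjusted over the list alone, 31 and 1 after quantile normalization and 34 and 1 after scaling to 1 median (median −0.35, adjusted p = 1.5e-05; adjusted p = 0.70 with an estimated correlation), and NOP58 fell by 1.84.

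Cell cycle genes were lower as a list. Of 35 regulators 8 fell and 4 rose, with the same counts adjusted over the list alone, 15 and 3 after quantile normalization and 15 and 2 after scaling to 1 median (adjusted p = 0.00022; adjusted p = 0.15 with an estimated correlation). The cyclin PCL1 fell by 2.25 and the S-phase cyclin CLB5 rose by 0.78. DNA replication and histones had 5 of 50 risen and 5 fallen, or 5 and 4 adjusted over the list alone, 4 and 17 after quantile normalization and 3 and 16 after scaling to 1 median (adjusted p = 0.023; adjusted p = 0.60 with an estimated correlation). RNR1, the major large subunit of ribonucleotide reductase, fell by 1.86 and RNR3 rose. Without day 22 replicate 1 the call of this list was lost.

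Several mitochondrial and stress lists were higher. Of 67 mitochondrial ribosomal proteins 48 rose and none fell, or 53 adjusted over the list alone, 32 after quantile normalization and 29 after scaling to 1 median (median 0.47, adjusted p = 6.1e-07; adjusted p = 0.54 with an estimated correlation), MRPL33 by 1.45 and MRPL37 by 1.35. In the respiratory chain and ATP synthase list 31 of 40 rose, or 32 adjusted over the list alone and 20 after scaling to 1 median (median 0.59, adjusted p = 8.2e-06; adjusted p = 0.60 with an estimated correlation), led by CYC7 (2.12) and QCR8 (1.73). The Msn2/Msn4 list had 29 of 45 genes risen, or 30 adjusted over the list alone, and 17 risen and 1 fallen after scaling to 1 median (median 0.49, adjusted p = 0.00044; adjusted p = 0.65 with an estimated correlation). For stationary phase and quiescence the count was 16 of 24, also adjusted over the list alone (median 0.67, adjusted p = 0.00066; adjusted p = 0.58 with an estimated correlation). Heat shock proteins and chaperones had 18 of 31 risen and 1 fallen, also adjusted over the list alone, and 10 and 2 after scaling to 1 median (adjusted p = 0.0067; adjusted p = 0.58 with an estimated correlation), where the constitutive chaperone SSA2 fell by 1.52 and SSA3 rose by 1.72.

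Of the genes followed by name, HSP26 rose by 0.79 (adjusted p = 0.0034) and HSP12 by 0.40 (adjusted p = 0.039), the latter not called after scaling to 1 median. TSL1, of trehalose synthesis (0.47), and the cytosolic catalase CTT1 (0.52) passed with the deposited scaling and under neither of the other scalings, and the glycogen synthase GSY2 (0.34) did not pass after scaling to 1 median. All 4 of these calls ended without day 22 replicate 2. Those of HSP12 and TSL1 ended also without day 22 replicate 1, those of HSP12, TSL1 and CTT1 without chemostat replicate 2, and that of HSP12 also without chemostat replicate 1 or either day 16 array. HSP104 (0.10, adjusted p = 0.12), the stationary phase gene SNZ1 (−0.12), the near-identical glucose transporters HXT6 (−0.08) and HXT7 (−0.30), the G1 cyclin CLN2 (−0.57) and ACT1 (−0.29, adjusted p = 0.85) did not pass, although CLN2 was called lower after quantile normalization.

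Smaller sets were also higher at day 22. In autophagy 22 of 35 genes rose and 3 fell, or 23 and 3 adjusted over the list alone, 15 and 5 after quantile normalization and 11 and 4 after scaling to 1 median (adjusted p = 0.022; adjusted p = 0.58 with an estimated correlation). ATG39, a receptor for selective autophagy (1.85), and ATG33, a mitochondrial protein needed for mitophagy (1.47), rose most. Meiosis and sporulation had 18 of 42 risen and 1 fallen, with the same counts adjusted over the list alone (adjusted p = 0.026; adjusted p = 0.45 with an estimated correlation), including SGA1, a sporulation-specific glucoamylase (2.20), and the sporulation kinase SPS1 (1.92). This call ended after quantile normalization and with only genes with a mean of at least 50. Phosphate starvation genes had 9 of 16 risen and 1 fallen, also adjusted over the list alone (adjusted p = 0.035; adjusted p = 0.48 with an estimated correlation), with GIT1 and the phosphate transporter PHO84 (1.68) highest. Without day 22 replicate 1 that list was not called. Trehalose and glycogen metabolism had 12 of 20 risen and 1 fallen, or 16 and 1 adjusted over the list alone and 5 and 2 after scaling to 1 median (adjusted p = 0.034; adjusted p = 0.60 with an estimated correlation). The glycogenin GLG2 rose by 2.02 and PGM1 fell by 1.58. The call was lost after scaling to 1 median and without chemostat replicate 2 or day 22 replicate 2. With the actin ratio as a covariate, an alternative added after the data were seen, the autophagy, meiosis, phosphate and trehalose lists were not called, nor were the phosphate and trehalose lists without the 2 arrays of lowest ratio. The phosphate and meiosis calls also ended with a floor of 50 and with genes at the floor everywhere kept, and that of phosphate with no floor. Of all lists called at day 22, fry did not call those for ribosome biogenesis, cytosolic ribosomal proteins, and DNA replication and histones.

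Camera called none of the other 12 lists at day 22, several of which held changes in both directions. Fry called 7 of them higher, those for the proteasome, oxidative stress, mating, beta-oxidation, the glyoxylate cycle, hexose transport and nitrogen. Fry does not compare with other genes, so the shift of all genes (median 0.23 as fitted) counts toward these calls. Proteasome and ubiquitin genes had 14 of 38 risen, or 12 adjusted over the list alone (adjusted p = 0.054), RPN4 by 0.81. This list was called higher in 16 of 27 alternative settings, among them quantile normalization (adjusted p = 0.0013) and fry (adjusted p = 0.0036), although 2 members rose and 1 fell after scaling to 1 median. Oxidative stress defence had 20 of 37 risen and 3 fallen, or 20 and 5 adjusted over the list alone and 12 and 6 after scaling to 1 median (adjusted p = 0.20, called after quantile normalization), with the glutathione peroxidase GPX1 at 2.26 and OYE3 at 1.62. Of the mating and pheromone response list 18 of 37 rose and 2 fell, with the same counts adjusted over the list alone, 16 and 6 after quantile normalization and 12 and 8 after scaling to 1 median (adjusted p = 0.17, called with the actin covariate), PRM3 by 2.32. Beta-oxidation and peroxisome genes had 16 of 42 risen and 4 fallen, also adjusted over the list alone, 11 and 6 after quantile normalization and 9 and 7 after scaling to 1 median (adjusted p = 0.36), with the carnitine carrier CRC1 at 1.73 and PEX18 at 1.59. In the list for the glyoxylate cycle, gluconeogenesis and alternative carbon 13 of 29 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.20). Beside FBP1 it holds SUC2, invertase, and the dicarboxylate carrier DIC1, which fell (−2.49 and −1.92). The tricarboxylic acid cycle had 7 of 19 risen and 2 fallen, or 8 and 2 adjusted over the list alone and 2 and 3 after scaling to 1 median (adjusted p = 0.90), and SDH3 rose by 1.40.

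Hexose transport had 4 of 14 risen, also adjusted over the list alone, and 3 risen and 2 fallen after quantile normalization (adjusted p = 0.72), among them the low-affinity transporter HXT1 (1.88) and HXT5 (1.70). For glycolysis and alcoholic fermentation 2 of 23 rose and 2 fell, or 1 and 2 adjusted over the list alone and 1 and 6 after scaling to 1 median (median 0.03 as fitted, mean −0.05, adjusted p = 0.12). The major pyruvate decarboxylase PDC1 fell by 1.27 and the minor isoform PDC6 rose by 0.71. In the cell wall list 13 of 47 rose and 9 fell, also adjusted over the list alone, and 8 and 11 after scaling to 1 median (median 0.11 as fitted against −0.12 relative to all genes, adjusted p = 0.43), PIR3 by 2.12, and FLO11 fell by 2.74. Nitrogen catabolite repression had 7 of 33 risen and 3 fallen, also adjusted over the list alone, and 6 and 8 under either other scaling (adjusted p = 0.77), with the oligopeptide transporter OPT2 at 2.26 and the proline oxidase PUT1 at 1.87. The 4 of 12 vacuolar protease genes that passed all rose, or 2 adjusted over the list alone, with 2 risen and 2 fallen after quantile normalization and 1 and 2 after scaling to 1 median (adjusted p = 0.93). Of 37 genes for RNA polymerase I and III 5 rose and 7 fell, or 5 and 6 adjusted over the list alone and 4 and 11 under either other scaling (adjusted p = 0.084). In the last 4 of these lists the fitted median or mean was above 0 while the test, which compares with all other genes, pointed lower. The median fell below 0 after quantile normalization for the nitrogen and polymerase lists, and after scaling to 1 median for the glycolysis, cell wall, nitrogen and polymerase lists.

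Non-coding RNAs as classes, set out after the data were seen, were mostly higher. Of 59 small nuclear and nucleolar RNAs 48 were higher at day 22 and none lower (median 1.46 relative to all genes), and of 88 tRNAs 76 were higher and none lower (0.96). At day 9 the counts were 35 higher and 1 lower, and 29 higher. The actin ratio was lowest on the arrays of the last days.

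At day 22 the number of changed genes was 1337 without day 22 replicate 2, the array with the lowest actin ratio. Without the 2 arrays of lowest ratio, day 16 replicate 2 and day 22 replicate 2, it was 1194, and with the ratio as a covariate it was 555. Of the 116 genes named for this comparison that passed, 92 passed with each array left out in turn and 57 passed with the covariate. With it, 18 ergosterol genes and 9 seripauperins still fell, while 3 mitochondrial ribosomal proteins, 3 respiratory chain genes and 6 Msn2/Msn4 genes rose and 5 amino acid biosynthesis genes fell. Median changes moved less than these counts. As fitted, they went from 0.71 to 0.58 for the mitochondrial ribosomal proteins and from 0.82 to 0.73 for the respiratory chain. They went from 0.72 to 0.59 for Msn2/Msn4, from −0.63 to −0.51 for amino acid biosynthesis and from 0.23 to 0.17 for all genes.

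Within the retentostat, most calls between consecutive days came between days 2 and 9. FIT2 (−3.78 ± 0.27 SE, adjusted p = 6.5e-05), FTR1 (−3.38 ± 0.23, adjusted p = 6.5e-05), SIT1 (−3.08), FIT3 (−2.59) and CYB5 (−2.31) fell most. The largest rises were those of SPG1 (2.76), the hydrophilin GRE1 (2.29), TPO2 (2.18), MF(ALPHA)2 (2.01) and HSP30 (1.95). There were 199 higher and 126 lower genes, 172 and 149 after quantile normalization, and 231 and 153 after scaling to 1 median. The count was 61 without day 2 replicate 2, 67 without day 2 replicate 1 and 98 without day 9 replicate 1. It was 202 without chemostat replicate 1, 203 without either day 22 array and 1074 without day 9 replicate 2. The calls of SPG1 and GRE1 ended without day 2 replicate 1 or day 9 replicate 1, that of FIT3 without either day 2 array, and that of HSP30 without any of these 3 arrays. The other 6 genes named here passed with each array left out in turn, but none passed when only the 4 arrays of these days were fitted.

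Later steps gave almost no calls when p-values were adjusted over all genes. Between days 9 and 16, limma called 1 gene higher, YKL183C-A, known only by its systematic name and singled out after its values were seen (2.69 ± 0.32, adjusted p = 0.024), with 487 genes at an unadjusted p under 0.05. No gene passed here without chemostat replicate 1, chemostat replicate 2 or day 16 replicate 2. There were 2 without chemostat replicate 3 or either day 22 array, 4 without either day 2 array, 45 without day 9 replicate 1 and 100 without day 9 replicate 2. Between days 16 and 22 limma called 0 genes, with 353 at an unadjusted p under 0.05. A floor of 50 gave 4 calls, keeping genes at the floor everywhere gave 3, and the other settings gave 0. Adjusted over their class alone, 29 of 59 small nuclear and nucleolar RNAs rose between days 9 and 16 and 0 fell (median 0.65 relative to all genes). Between days 16 and 22, 1 of them rose. Of 88 tRNAs, 0 passed in this way between days 9 and 16, and 2 rose between days 16 and 22. These classes were set out after the data were seen.

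Over the whole retentostat period, from day 2 to day 22, the largest falls of named genes included several of iron uptake. Relative to the median of all genes, they were those of FIT2 (−3.36 ± 0.27 SE, adjusted p = 6.0e-05), FTR1 (−3.12 ± 0.23, adjusted p = 5.7e-05), SIT1 (−3.09), FIT3, which like FIT2 holds siderophore-bound iron (−2.99), CYB5 (−2.99 ± 0.29, adjusted p = 0.00018), SCM4 (−2.89) and IZH4 (−2.80). The largest rises of protein-coding genes were those of FBP1 (2.96 ± 0.19, adjusted p = 1.1e-05), TPO2 (2.90 ± 0.26, adjusted p = 6.0e-05) and GIT1 (2.73 ± 0.25, adjusted p = 6.0e-05), the last chosen after its values were seen, as were MOR1 (2.59), the acyl-CoA synthetase FAA1 (2.39) and AAD10 (2.32). SNR45 (4.55), SNR71 (3.95) and SNR128 (3.66) rose more than these. As fitted, SNR3 was at least 10.4-fold higher than the floor it occupied at day 2, SNR63 at least 8.49-fold, SNR35 at least 6.35-fold and GAT4, a GATA family gene, at least 4.79-fold.

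Sterol genes again moved as a block. Of 25 ergosterol genes 21 fell, or 22 adjusted over the list alone (median −1.46 relative to all genes, adjusted p = 7.0e-27; adjusted p = 0.052 with an estimated correlation). All 10 seripauperins fell, also adjusted over the list alone (−1.89, adjusted p = 1.3e-11; adjusted p = 0.43 with an estimated correlation); after quantile normalization 9 did. In the list for anaerobic cell wall and sterol uptake 9 of 24 fell and 1 rose, or 10 and 2 adjusted over the list alone (adjusted p = 2.1e-06; adjusted p = 0.052 with an estimated correlation). The riser, AAC3, passed under neither of the other scalings, nor without either of chemostat replicates 1 and 2 or any of the day 2 and day 22 arrays. Mitochondrial ribosomal proteins had 25 of 67 risen, or 39 adjusted over the list alone, 13 after quantile normalization, 8 after scaling to 1 median and 0 with the actin covariate (median 0.34, adjusted p = 9.0e-07, and adjusted p = 0.54 with an estimated correlation), and MRPL37 rose by 1.06. As fitted, the median of this list was 0.53 without the covariate and 0.45 with it.

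Translation-related lists were lower than other genes, with few single calls. Amino acid biosynthesis had 6 of 79 fallen, or 4 adjusted over the list alone, 10 after quantile normalization and 15 after scaling to 1 median (adjusted p = 4.2e-09; adjusted p = 0.51 with an estimated correlation). ASN1 fell (−1.50), a call lost without day 2 replicate 1 or either day 22 array. For translation factors the count was 4 of 35, also adjusted over the list alone, and 7 under either other scaling, with HYP2 (−2.13) lowest (list adjusted p = 4.9e-06; adjusted p = 0.48 with an estimated correlation). Aminoacyl-tRNA synthetases had 1 of 21 fallen, ARC1 (−0.86), and 0 adjusted over the list alone, 4 after quantile normalization and 6 after scaling to 1 median (adjusted p = 8.2e-06; adjusted p = 0.58 with an estimated correlation). Of the fits with 1 array left out, only those without day 9 replicate 1 or day 9 replicate 2 kept the ARC1 call. Cytosolic ribosomal proteins were lower as a list (median −0.34, adjusted p = 3.6e-05; adjusted p = 0.70 with an estimated correlation), not called after quantile normalization, while the 2 members that passed, RPS14B (0.81) and RPS22B (0.71), rose, or 1 adjusted over the list alone. Both of these calls ended without day 2 replicate 1 or day 22 replicate 2, and that of RPS14B also without day 22 replicate 1 and after scaling to 1 median. Ribosome biogenesis had 1 of 131 risen and 1 fallen, and 0 adjusted over the list alone, with 6 fallen after quantile normalization and 5 after scaling to 1 median (adjusted p = 0.00050; adjusted p = 0.74 with an estimated correlation). Glycolysis and alcoholic fermentation was lower with 1 of 23 risen and 1 fallen, PDC1 (−1.01), also adjusted over the list alone (adjusted p = 0.024; adjusted p = 0.60 with an estimated correlation). The list call was lost after quantile normalization and without the 2 arrays of lowest actin ratio, and both it and that of PDC1 without day 2 replicate 1 or day 22 replicate 2.

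Phosphate starvation genes were higher, with 8 of 16 risen, or 8 risen and 1 fallen adjusted over the list alone (adjusted p = 0.023; adjusted p = 0.47 with an estimated correlation), GIT1 and PHM6 (1.73) most. This call ended with no floor and with only the arrays compared. So were genes for meiosis and sporulation, with 10 of 42 risen and 1 fallen, also adjusted over the list alone, and 5 and 6 risen after quantile normalization and scaling to 1 median (adjusted p = 0.030; adjusted p = 0.45 with an estimated correlation). SPS1 rose by 1.62, and the sporulation kinase SMK1 was at least 3.33-fold higher than the floor it occupied at day 2. This list was not called after quantile normalization, without day 2 replicate 1 or with a floor of 50. It was also lost with only genes with a mean of at least 50, with genes at the floor everywhere kept, and with trend and robust moderation, and with the actin ratio as a covariate neither it nor the phosphate and glycolysis lists were. Of the lists called between days 2 and 22, fry called those for ergosterol, seripauperins, anaerobic cell wall, mitochondrial ribosomal proteins, phosphate and meiosis.

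The stress lists that were higher at day 2 were not called between days 2 and 22, with 3 of 45 Msn2/Msn4 genes risen (adjusted p = 0.75) and 3 of 31 heat shock genes risen and 1 fallen (adjusted p = 0.91). Adjusted over the list alone, 1 Msn2/Msn4 gene rose, while 3 rose and 2 fell after quantile normalization and 0 rose and 2 fell after scaling to 1 median. For heat shock these counts were 1 and 1, 4 and 1, and 1 and 1. Their medians as fitted were 0.12 and 0.15, while the test pointed lower than other genes. After quantile normalization the heat shock list was called higher (adjusted p = 0.048). Stationary phase and quiescence had 6 of 24 risen, or 8 adjusted over the list alone and 2 risen and 1 fallen after scaling to 1 median (median 0.56 as fitted, adjusted p = 0.17), and was called higher after quantile normalization (adjusted p = 0.0054). Among other genes, HXT1 (2.16), CRC1 (1.81), OPT2 (2.01), PRM3 (1.85) and the galactose permease GAL2 (1.45) rose, and SUC2 fell (−1.69), a call lost without day 22 replicate 2.

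In all, 756 genes were higher and 181 lower between days 2 and 22 (80.7% higher), 479 and 341 after quantile normalization (58.4%), and 347 and 330 after scaling to 1 median (51.3%). Without day 22 replicate 2 the count of 937 became 245. It was 353 without day 2 replicate 1, 554 without day 22 replicate 1 and 579 without day 2 replicate 2. Of 90 genes named for this comparison that passed, 34 passed with each array left out in turn and 26 with the actin ratio as a covariate.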

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

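Chosen only after the result was seen were the tests of the non-coding RNAs, of oxygen entry and of cross-hybridisation, and every use of the actin ratio as a covariate. The rule for oxygen entry was also changed after its outcome was known.

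Ribosomal RNA control probe sets, on which the comparisons do not report, drew attention because almost all retentostat arrays lay above every chemostat array. A 25S probe set averaged 630 over the retentostat arrays and 84.2 over the chemostats, with 7 of 8 arrays above the highest chemostat value of 114.6. An 18S probe set averaged 145 against 39.2 and another 123 against 51.6, with 8 of 8 arrays above. The spike-in probe sets of day 9 replicate 1 stood at 2.14-fold of the chemostat mean, and 7 of 8 retentostat arrays lay above the highest chemostat at 1.05-fold. Of 2255 probe sets above the floor with no gene or several genes, also outside the comparisons, 700 were higher at day 22 than in the chemostat and 273 lower.

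A difference between groups was the last to draw attention. Of 27 genes called both at day 2 against the chemostat and between days 2 and 22, 9 changed in opposite directions. As fitted, these were AAC3 (−1.17, then 0.93), ALD6 (−2.32, then 0.75), CHS2 (−0.89, then 0.58), DSE3 (−0.74, then 0.66), HXT2 (−2.48, then 1.56), MEP3 (−1.44, then 1.94), PHD1 (−0.83, then 0.79), RPS22B (−0.82, then 0.90) and the ribosomal RNA gene RDN37-1 (1.37, then −1.18). Both comparisons use the day 2 arrays with opposite signs, so noise in those arrays alone pushes the changes apart. The opposition itself was not tested.

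Non-coding RNAs were higher at day 22 than in the chemostat, 128 of 154 with none lower and a median log2 change of 1.45. Changes in this and the next paragraph are as fitted. Array scaling is argued against as the whole cause, since this median exceeded the mean change of the 9 spike-in probe sets (0.42, SD over probe sets 0.15) by 1.03. The spike-in change was 0.18 on day 22 replicate 1 and 0.67 on replicate 2. RNA degradation as read from the actin ratio is also argued against as the whole cause for days 9 and 16. Day 9 replicate 2 and day 16 replicate 1 had a ratio not below the lower day 2 array. Their medians were 0.95 and 1.14, against 0.06 and 0.40 on the day 2 arrays. For day 22 the median was 1.28 with the ratio as a covariate, although 60 instead of 128 passed, with a median SE of 0.39 instead of 0.25. That fit takes its slope from arrays of the same group. It cannot separate the ratio from other differences between them, so it does not decide the question for day 22. Time and growth rate stay open, untested, as does the amount of messenger RNA per cell. Whether the 1-cycle labelling captured these RNAs alike on all arrays was not tested either, so the values are array signal and may not reflect abundance.

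Sterol and anaerobic genes were lower at day 22 than at day 2. Oxygen entry stays open, since the haem-activated genes had a median change of 0.0827 with quartiles of −0.38 and 0.24 (1 of 11 higher, 2 lower), while against the chemostat 6 were higher and 2 lower at day 22 (median 0.62). The genes lower than at day 2 were YHB1, whose probe sets ranged from −1.96 to 2.02, and HYP2, which has a close copy; over the 9 other genes the median was 0.09 and the upper quartile 0.29, with 1 higher and 0 lower. In 5 pairs of genes with an aerobic and a hypoxic form, 0 aerobic partners rose and 2 fell, while 1 hypoxic partner rose and 0 fell. The median aerobic minus hypoxic change was −0.96. These pairs lean against oxygen entry, but on few calls, and probe sets may not separate close copies such as HYP2 and ANB1. The haem-activated genes against the chemostat do not go against it, so that question is not settled. Cross-hybridisation within the seripauperins stays open, since 0 of the 10 are on a probe set that is not shared within a gene family, and their calls could share 1 signal. With the actin ratio as a covariate the median of the ergosterol genes was −1.27, and 12 instead of 21 passed as the median SE went from 0.20 to 0.28. Only 1 of 10 seripauperins passed then, with a median of −1.69. The slope of the covariate comes only from arrays of the same group. These differed most at days 16 and 22, where replicate 2 was lower both times. The fit therefore cannot separate the ratio from other differences between these arrays, and degradation stays open. Time and growth rate stay open, untested.

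More genes were higher than lower at day 22 than in the chemostat, 74.7% of the calls. Non-coding RNAs among the tested genes are argued against as the source, since 73.0% of the calls among protein-coding genes were higher. The share was 54.6% after quantile normalization and 47.4% after scaling to 1 median, but both centre all genes near 0, which by itself brings the split close to even. The mean change of the 9 spike-in probe sets, used above to measure scaling, was 0.42 (SD over probe sets 0.15). It was larger than the median change of all genes, 0.23, so scaling stays a possible source of the excess. This rests on day 22 replicate 2, where the spike-in change was 0.67, against 0.18 on replicate 1. Without replicate 2 the median change of all genes was 0.20. The SD over probe sets does not measure this difference between arrays. The scaling of each array to 1 target and a general change with time or growth rate still cannot be told apart here, and messenger RNA per cell was not tested.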

How the results depend on the processing

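Chosen only after the results were seen were the settings without the 2 arrays of lowest actin ratio, with that ratio as a covariate, and with nuclear protein-coding genes only. For named genes, 6947 results kept their direction and side of the threshold, 999 were weaker, 14 stronger and 0 reversed. For lists the counts were 2333, 123, 53 and 2. Unless a reason is given, the cause was not tested. Low signal over background limits genes near the floor, whose changes are lower bounds, and 2 arrays per day limit all comparisons.

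Genes called at day 2 against the chemostat (87) were 57 after scaling to 1 median, 45 with no floor, 49 with no filter on dim genes, 47 with every probe set on its own, 56 at 2-fold or more and 0 with only the arrays compared, a fit with few degrees of freedom. Between days 9 and 16 (1 call) there were 0 with no floor, 6 with a floor of 50, 0 with no filter on dim genes, 2 with every probe set on its own, 3 with trend and robust moderation, 8 with culture as random block and 0 with only the arrays compared. Between days 16 and 22 (0 calls) there were 4 with a floor of 50 and 3 with no filter on dim genes. With only the arrays of the groups compared, 0 genes were called between days 2 and 9 and 473 between days 2 and 22. Requiring at least 2-fold, by construction a stricter rule, gave 776 at day 9, 845 at day 16 and 948 at day 22 against the chemostat, 169 between days 2 and 9 and 405 between days 2 and 22.

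Leaving out both arrays with the lowest actin 5' to 3' ratio, which also leaves fewer arrays, gave 1042 genes with any change over the 5 groups, 64 with any change over days 2 to 22, 2 at day 2, 995 at day 16 and 1194 at day 22 against the chemostat, 68 between days 2 and 9 and 193 between days 2 and 22. With the actin ratio as covariate the counts were 1229 for any change over the 5 groups, 191 for any change over days 2 to 22, 55 at day 2 and 555 at day 22 against the chemostat, and 149 between days 2 and 22.

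With a replicate block, 143 genes were called at day 2 against the chemostat and 3 between days 9 and 16; no other count moved by over 1.5 times. Lists no longer called were DNA replication and histones at day 2 and day 22, oxidative stress defence at day 2, and autophagy and phosphate starvation at day 22; the cell wall list was called lower at day 2. Culture as random block likewise took the replicate number of a retentostat array as its culture. In the other settings the replicate numbers were not taken to pair the arrays. In 5 of 6 pairs of days the same-number arrays correlated with r over 0.1 (0.0656 to 0.394), and 6 of 8 retentostat arrays were closer to their own number.

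Camera with estimated correlation called 0 lists at day 2 and 0 at day 22 against the chemostat and 0 between days 2 and 22. The fry rotation test called 8 lists at day 2. Reversed were heat shock proteins and chaperones between days 2 and 22, higher after quantile normalization (0.20, adjusted p = 0.048), and nitrogen catabolite repression at day 22 against the chemostat, higher in the fry rotation test (mean minus other genes 0.000279, adjusted p = 0.015), which does not compare with other genes.

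With each array left out in turn, the counts ranged from 1427 to 2778 over the 5 groups, 202 to 1366 over the retentostat days, 4 to 158 at day 2, 1250 to 2227 at day 9, 1181 to 2526 at day 16 and 1337 to 2650 at day 22 against the chemostat. They ranged from 61 to 1074 between days 2 and 9, 0 to 100 between days 9 and 16, 0 to 0 between days 16 and 22 and 245 to 1171 between days 2 and 22. Lists called ranged from 16 to 20 at day 2, 18 to 21 at day 22 and 11 to 13 between days 2 and 22. Where this leaves a day with a lone array, that array is assumed to vary like the other groups.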

Other observations

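All of the lists in this part were set out after the data were seen.

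Several iron uptake genes fell between days 2 and 9. Of 27 genes of the Aft1 iron regulon, 0 passed at day 2 against the chemostat, while between days 2 and 9 9 fell and none rose, or 12 fell and 1 rose adjusted over the list alone (median −0.36). Between days 9 and 16 and between days 16 and 22, 0 of these genes passed. Against the chemostat 8 fell and 2 rose at day 9, and 7 fell and 5 rose at day 22. The set as a whole was not tested. FIT3 had an intensity of 5873 ± 44.4 (SD, n = 2) at day 2 and 1020.4 ± 411 at day 9, and SIT1 went from 485 ± 63.1 to 57.6 ± 9.12.

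Several glucose-repressed genes rose. Of 12 genes that are repressed by glucose or induced when it is low, 2 rose at day 2, 5 rose and 1 fell at day 9, and 6 rose and 1 fell at day 22 against the chemostat. HXT2, a transporter for low glucose that is not among these 12 genes, fell at day 2. It stood at 261 ± 142 (n = 3) in the chemostat, 41.0 ± 0.707 (n = 2) at day 2 and 122 ± 22.1 at day 22. The alpha-factor gene MF(ALPHA)1, in a strain the labels give as MATa, had an intensity of 164 ± 25.7 in the chemostat and 1891 ± 223 at day 22. Of 14 protein genes of the mitochondrial genome 6 were higher at day 22 than in the chemostat, with a median change of −0.09 relative to all genes.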
